A study of Mus musculus with 2 samples.

How the data were processed

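H3K36me3 ChIP-seq peak lists of embryonic day 16.5 mouse intestine were read for 2 biological replicates of 1 group. Besides the list of each replicate, a pooled list and a list of replicated peaks were deposited, with 123400 and 55596 peaks. Per the labels, the tissue came from embryos of both sexes of strain B6NCrl, and a possible control experiment is named. The deposited notes state that the lists were made from alignments to mm10 and from further input files that the notes do not describe, 1 listed for both replicates and 1 for replicate 1 and the pooled list only. The aligner, the peak caller and their versions are not given in the sources used here. Each peak has a start, an end and a summit offset in bases. The score of a peak, as deposited, runs from 10 to 1000 and scales the caller's p to the best peak of the list. The fold value, as deposited by the authors, is the ratio of ChIP over control signal at the peak. The authors' columns of significance hold -log10 of the peak's p and q values. The files analysed here hold no read counts, so depth per sample is unknown, and no interval that needs it is given.

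Genes were taken from GENCODE vM21 and sequence from GRCm38.p6. The gene set was the 21058 protein-coding genes on chromosomes 1 to 19 and X with a body of at least 1 kb, the body running from the first to the last annotated base. Overlapping peaks of a list were merged. Coverage of a body was its percentage of bases under merged peaks, and a gene was called marked at 10% or more in both replicates. Signal of a body was the sum of fold value times bases, divided by body length. Values are given per replicate or as mean and SD (n = 2). Wilson intervals of shares have a level of 95% and cover counting error over genes only. The sequences outside these chromosomes were left out of all comparisons and are given as peak counts only.

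The share of peak bases in gene bodies was compared with 1000 circular shifts of the peaks along each chromosome, two-sided. Coverage of the body parts 3' and 5' of the midpoint, and of exons and introns, was compared in marked genes by a two-sided sign-flip permutation test with 100000 flips over the 20 chromosomes. A peak was called shared when at least 50% of its length was under peaks of the other replicate, with 200 shifts for chance. Domains were merged peaks joined over gaps of up to 3 kb. The number of marked members of each of 29 gene lists was compared with 10000 random lists of the same size matched on length in 20 classes, two-sided, with Benjamini-Hochberg adjustment over the 29 lists and a threshold of 0.05. The lists cover cell types of the gut, other organs, general cell machinery, imprinted genes, Hox genes, chemoreceptors and zinc finger genes. A gene list test describes these libraries, since genes are not replicates.

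The gene lists, tests, thresholds and the rule for named genes were chosen before the data were examined. By that rule, up to 3 genes with the highest and up to 2 with the lowest coverage were taken per list, with the 10 genes of at least 5 kb with the highest signal in both replicates. The rule added 5 genes per direction that differed most between replicates among those under 10% in one of them, the 3 longest domains found in both, Setd2, and the noncoding genes Xist, Malat1, Neat1, H19, Meg3 and Kcnq1ot1. Members that added nothing were left out. The alternatives set at the same time were stricter peak thresholds (-log10 q of at least 2, fold of at least 3), joining of gaps up to 1 kb or 3 kb, other overlap rules for shared peaks, each replicate alone, the pooled and replicated lists, other gene sets, other thresholds for marked genes (5%, 25%, 50%, any peak), introns without the first, and lists rotated along the genome. Autosomal genes only, and random lists matched on GC content or on GC content and repeats besides length, were added after the data were seen.

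The code was tested on simulated data. All of 1000 planted genes were marked and 0 of 15429 others. A planted ratio of 2 between the 3' and 5' parts came back as 2.00, and a planted exon over intron ratio of 3 as 2.78. With no planted difference the ratios were 0.997 and 0.992. Of 200 random lists 0 were called, and 29 of 29 lists with planted members were. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.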

Results

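H3K36me3, a histone modification deposited across the bodies of transcribed genes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the intestine of mouse embryos of strain B6NCrl at embryonic day 16.5. The samples formed 1 group of 2 biological replicates from embryos of both sexes, and replicate 2 was pooled from 41 embryos. No second group was profiled, so the comparisons below are between replicates and between genes, chromosomes and gene groups within this tissue. Replicate 1 had 106457 peaks and replicate 2 had 108380, which covered 30.6 and 30.2 Mb, or 1.15% ± 0.0104 (SD, n = 2) of chromosomes 1 to 19 and X on mm10. The median peak was 234 bases long in replicate 1 and 226 in replicate 2, with median fold values over control of 3.32 and 3.33. The deposited lists were permissive, with a lowest -log10 q of 0.305 and 0.319. Only 48.6% of peaks in replicate 1 and 46.2% in replicate 2 had a -log10 q of at least 2. The files analysed here were peak lists, which hold no read counts, so the sequencing depth is unknown. Coverage here is the percentage of a region's bases under peaks.

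Most genes with at least 10% of the body under peaks in one replicate reached that level in the other, 82.2% of 4047 in replicate 1 and 84.0% of 3962 in replicate 2. Across 21058 protein-coding genes of at least 1 kb, gene-body coverage in replicate 1 and replicate 2 correlated with Pearson's r = 0.907 and Spearman's rho = 0.895, with 8841 genes at 0 in both; this is a correlation across genes, and genes are not independent replicates. Of the bases under a peak in either replicate, 20.9% were under peaks in both, against at most 0.879% when 1 list was shifted along the chromosomes. Of the peaks, 31.9% in replicate 1 and 32.2% in replicate 2 (mean 32.0%) had at least 50% of their length under peaks of the other replicate. Both shares come from the same pair of lists, so they are not independent. The highest share after shifts was 1.53%. Peaks in the lowest quartile of fold values were shared in 23.6% and 24.9% of cases, and those in the highest quartile in 44.4% and 46.0%. Joining peaks across gaps of up to 3 kb raised the overlap of bases to 46.8%. Among 17694 genes of at least 5 kb, 13 had under 10% coverage in one replicate and at least 25% in the other. Examples were Ngdn, with 32.7% in replicate 1 and 6.13% in replicate 2, and Cdk5, with 0% and 25.7%.

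H3K36me3 peaks lay almost entirely inside genes and in the downstream part of them. Protein-coding gene bodies held 93.6% ± 0.284 (SD, n = 2) of peak bases, 2.29 ± 0.00809 times the share after circular shifts. Introns held 66.1% ± 0.388 of peak bases, exons 27.6% ± 0.104, and sequence outside all annotated genes 5.38% ± 0.254, although the latter makes up 53.9% of these chromosomes. The permutation p for gene bodies was 0.002 in each replicate, two-sided, the smallest that 1000 shifts can give.

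Within marked genes, those with at least 10% of the body under peaks in both replicates, coverage was lowest at the 5' end and rose toward the 3' end. It was 2.16% ± 0.0435 (SD, n = 2) in the first of 10 equal bins, 31.9% ± 0.194 in bin 9 and 27.8% ± 0.411 in bin 10. It fell to 18.3% ± 0.308 in the first kilobase past the annotated 3' end and to 5.94% ± 0.00523 in the fifth. The part of the body 3' of its midpoint had 1.95 ± 0.0335 times the coverage of the part 5' of it. Exons had 27.5% ± 0.328 coverage and introns 16.2% ± 0.384, a ratio of 1.70 ± 0.0200. The exon over intron ratio took no account of position along the body, so it may not be separate from the rise toward the 3' end. Both ratios were above 1 on 20 of 20 chromosomes in each replicate, with a two-sided permutation p of 1e-05 from sign flips over chromosomes, the smallest that 100000 flips can give. For exons over introns the call ended when marked genes were defined at 50% coverage, with a ratio of 1.11 over the 8 chromosomes with a value and a permutation p of 0.359, and the p ranged from 1e-05 to 0.359 over the alternatives.

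**Figure D1:**
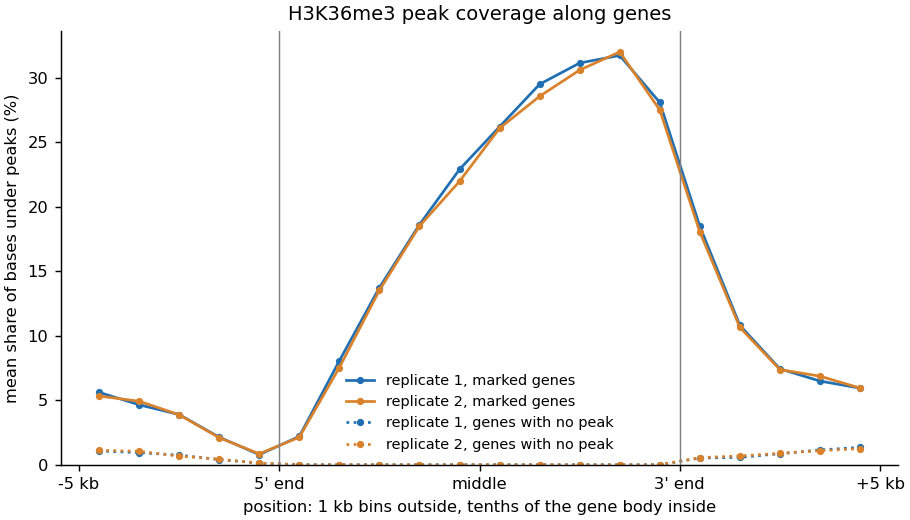
Mean percentage of bases under H3K36me3 peaks along protein-coding genes, in 10 equal bins of the body and in 1 kb bins of the 5 kb on each side, with 1 line per replicate. Marked genes rose from 2.16% in bin 1 to 31.9% in bin 9; genes with no peak in either replicate are at 0 within the body by definition.

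The longest peak domain present in both replicates, with gaps of up to 3 kb joined, lay over all but the 5' part of Gtf2i (134237834 to 134314760, minus strand), which encodes a general transcription factor. It ran over 56.7 kb of chromosome 5, from 134236941 to 134293639, with 43.9% of its bases under peaks in replicate 1 and 44.3% in replicate 2. That end came from replicate 2, where the next peak began at 134296974. Peaks continued in the 5' part of the gene, up to 134311606 in replicate 1 and 134311378 in replicate 2. The next longest domain lay in Lrp1, an endocytic receptor gene, from 127538994 to 127594163 on chromosome 10, with coverage of 32.4% and 33.8%. The third spanned Sptan1 and Wdr34, which encode a spectrin chain and a dynein intermediate chain, from 29978744 to 30032507 on chromosome 2, with 41.9% and 39.2%. Of the 19003 domains found in both replicates, 1425 were at least 10 kb long and the median was 1.44 kb.

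**Figure D2:**
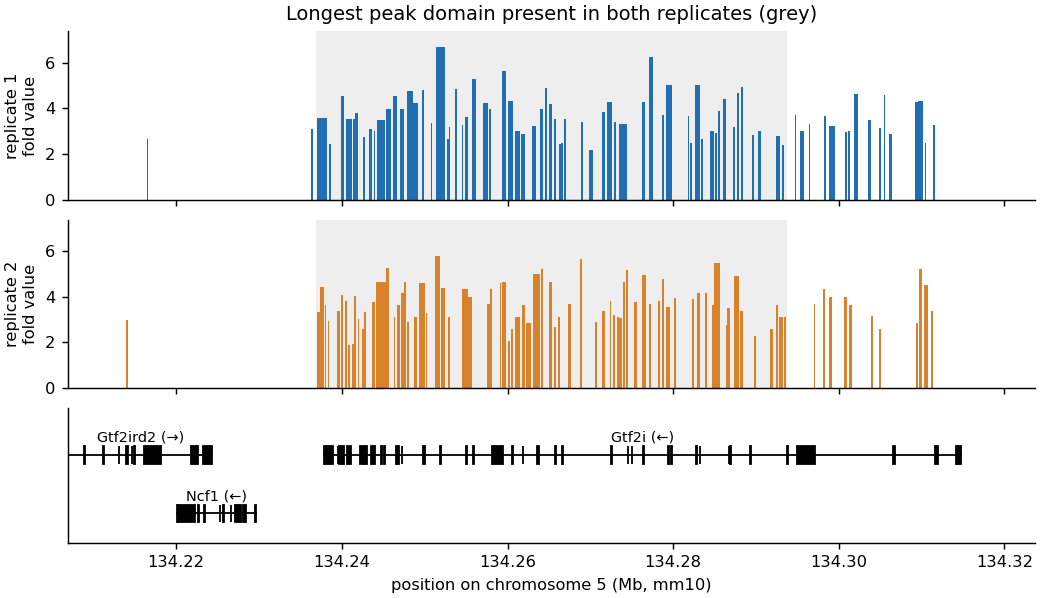
Peaks over the longest shared domain on chromosome 5, with position in Mb on the x axis, the fold value of each peak on the y axis, 1 panel per replicate, and gene models below (boxes are exons, arrows the direction of transcription). The grey domain holds 63 peaks in replicate 1 and 74 in replicate 2, lies over all but the 5' part of Gtf2i, and does not reach Gtf2ird2 or Ncf1. Both replicates also have peaks in that 5' part, outside the domain.

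Of 21058 protein-coding genes, 3327 (15.8%) were marked, against 761 expected had the replicates marked genes independently. Polrmt, which encodes the mitochondrial RNA polymerase (chromosome 10, 79736123 to 79746581), headed the 10 genes with the highest peak signal in both replicates, with 67.4% ± 4.44 (SD, n = 2) of its body covered. Zinc finger genes filled most of the other places. Zfp110 (chromosome 7, 12834761 to 12850577) had 66.2% ± 1.14, Zfp68 58.3% ± 5.42 and Repin1, which overlaps another gene, 57.0% ± 12.3. A peak was present in both replicates in 10133 genes, and 8841 had no peak in either. Here and below, the peaks of such a gene in the 2 replicates need not overlap. Replicate 1 alone marked 4047 genes and replicate 2 alone 3962. The count depended on the definition, from 5612 at 5% coverage to 621 at 25% and 14 at 50%, and was 1548 with peaks of -log10 q of at least 2, 6323 with gaps of up to 3 kb joined and 5038 in the pooled list.

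Genes of general cell machinery carried the mark more often than chance in both replicates, from 2.44 times for respiratory complex I to 5.85 times for ribosomal proteins. The chance level was taken from random lists of genes matched on length. Ribosomal protein genes were marked in 47 of 70 cases against 8.03 expected, and spliceosome genes in 30 of 40 against 8.09. Proteasome genes were marked in 20 of 31 cases against 5.86, cell cycle genes in 22 of 30 against 6.12, and genes of respiratory complex I in 15 of 35 against 6.15. Examples with coverage as mean and SD (n = 2) were Rps5 (51.4% ± 14.9), the core splicing factor gene Prpf8 (47.2% ± 2.96), the proteasome lid gene Psmd7 (36.6% ± 0.883), the complex I gene Ndufb8, which overlaps another gene (39.2% ± 0.638), and the mitotic kinase gene Cdk1 (32.9% ± 4.05). Not every member was covered: Rpl15, Rps21 and the replication clamp gene Pcna had 0% in both replicates. The adjusted permutation p over the 29 lists was 0.00258 for complex I and 0.000725 for the other 4, the latter the smallest these permutations gave, and all 5 lay above chance in each replicate alone. At 50% coverage all 5 lists had 0 marked members. Complex I also lost its call at 25% coverage (1 marked), at fold 3 (9) and at -log10 q of at least 2 (4), with adjusted p between 0.000483 and 1 over the alternatives.

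Genes for the enzymes and readers of H3K36 methylation were themselves often marked, with 12 of 19 against 2.46 expected (adjusted permutation p = 0.000725) and a peak in both replicates in 19 of 19. Kdm4a, a demethylase of this residue (chromosome 4, 118136957 to 118180043), had 39.3% ± 1.95 (SD, n = 2) coverage and Supt6, a histone chaperone that travels with RNA polymerase II, had 27.1% ± 1.68 and overlaps another gene. Setd2, which encodes the main H3K36 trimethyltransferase (chromosome 9, 110532597 to 110618633), had 11.6% ± 1.94. The de novo DNA methyltransferase gene Dnmt3b was close to uncovered at 1.97% ± 0.674. The call of this list ended at 50% coverage (0 marked) and at -log10 q of at least 2 (4 marked), with adjusted p between 0.000483 and 1 over the alternatives.

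Zinc finger genes named Zfp were marked in 136 of 365 cases against 74.9 expected, and a peak was present in both replicates in 262. The adjusted permutation p was 0.000725, the smallest these permutations gave, and the list lay above chance in each replicate alone. Zfp869, on chromosome 8, had 63.7% ± 1.27 (SD, n = 2) coverage. Chromosome 7 held 45 of the marked genes among 89, chromosome 8 held 14 of 24, and chromosome 4 held 5 of 30. None of the 7 on X was marked. With coverage measured on introns alone, 75 of 351 were marked against 59.5 expected (permutation p = 0.03), and on intron bases at least 500 bases from exon edges 56 of 328 against 34.6 (permutation p = 0.0002).

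Genes that define the cell types of the gut wall were marked no more often than chance, and few of them reached 10% coverage in both replicates. The 5 that did were Smtn and Tagln, which encode smooth muscle cytoskeletal proteins, the Hedgehog receptor gene Ptch1, the fibronectin gene Fn1, and Axin2, a feedback target of Wnt signalling. Coverage of Smtn, Tagln, Fn1 and Axin2 was 22.8% ± 4.37, 11.6% ± 0.395, 13.5% ± 0.777 and 17.2% ± 4.34 (SD, n = 2), and that of Ptch1 was 21.1% in replicate 1 and 16.9% in replicate 2. Tagln overlaps another gene. Smooth muscle genes were marked in 2 of 15 cases (2.25 expected), gut mesenchyme in 2 of 23 (3.17) and stem and progenitor genes in 1 of 14 (1.39). Secretory epithelium had 0 of 21 marked, brush border enzymes and transporters 0 of 16, enteric neurons and glia 0 of 20 and mesothelium 0 of 8. None of these 7 lists differed from chance, with adjusted permutation p between 0.146 and 1. Those with 0 marked, the lowest count possible, had an unadjusted permutation p of 0.0706 or more, so they could not lie below chance.

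Absorptive and general epithelial genes had 0 of 28 marked against 4.37 expected, below chance with an adjusted permutation p of 0.0443. Most of them nevertheless carried some signal: 17 of 28 had a peak in both replicates, where 12.1 were expected (adjusted permutation p = 0.0812). Vil1, the gene for the microvillus protein villin (chromosome 1, 74409376 to 74435559), which overlaps another gene, had 8.56% ± 1.80 (SD, n = 2) coverage and the epithelial keratin gene Krt8 had 7.24% ± 1.82. The call below chance was not kept in replicate 1 alone (1 of 28, adjusted permutation p = 0.0696), nor under 11 of the other 17 alternatives. Over all 18 the adjusted p ranged from 0.00896 to 1, and with gaps of up to 3 kb joined (9 marked against 8.09) or any peak counted the direction turned.

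With a peak in both replicates as the measure, 3 of these gut lists lay below chance. Smooth muscle had a peak in 12 of 15 genes (7.81 expected, adjusted permutation p = 0.0512), mesenchyme in 14 of 23 (10.3, p = 0.157), stem and progenitor genes in 10 of 14 (7.96, p = 0.395) and brush border genes in 8 of 16 (9.84, p = 0.480), none of which differed from chance. Secretory epithelium, with 2 of 21, enteric neurons and glia, with 2 of 20, and mesothelium, with 0 of 8, lay below chance, at adjusted permutation p of 0.00689, 0.00207 and 0.00619. The differences between these lists were not tested.

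Markers of blood vessels and blood were sparsely covered. Endothelial genes were marked in 0 of 17 cases and erythroid genes in 0 of 13, and immune genes in 1 of 18, the macrophage gene Cd68, with 30.6% and 71.6% coverage in replicates 1 and 2. These counts did not differ from chance (adjusted permutation p = 0.195, 0.226 and 0.666). For endothelial and erythroid genes, 0 is the lowest count possible. It gave unadjusted permutation p of 0.114 and 0.159, so neither list could lie below chance by this measure. With any peak counted, endothelium (4 genes, 9.29 expected) and erythroid cells (2, 6.17 expected) lay below chance, with adjusted permutation p of 0.0188 and 0.0319, and immune cells (4, 7.28 expected) did not (0.153).

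Markers of other organs rarely had an H3K36me3 peak in both replicates. Some had a peak in 1 replicate only, such as Nppa, with 0% coverage in replicate 1 and 12.9% in replicate 2. No gene was marked among 12 of pancreas, 16 of liver, 11 of stomach, 18 of brain neurons, 20 of heart and skeletal muscle, 13 of germ cells and 20 patterning transcription factors of other organs. A peak in both replicates was found in 0 pancreas, 0 liver, 0 stomach, 2 brain, 2 heart and muscle, 1 germ cell and 0 patterning genes, where 4.42, 7.48, 4.25, 9.19, 7.41, 5.75 and 9.72 were expected. All 7 lists lay below chance by this measure, with adjusted permutation p between 0.000483 and 0.0142. At 10% coverage none of the 7 did, with adjusted permutation p between 0.0880 and 0.277. For the lists other than liver no call below chance was possible there, since 0 marked is the lowest count. Even at that count their unadjusted permutation p was 0.0512 or more. Liver markers lay below chance in each replicate taken alone, with 0 of 16 marked and adjusted permutation p of 0.0480 and 0.0478, over a range of 0.000483 to 1 for all alternatives.

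Olfactory receptor genes were marked in 0 of 1029 cases, where 164 were expected, and vomeronasal receptor genes in 0 of 273, where 54.2 were expected (adjusted permutation p = 0.000725 for each). None of either family had a peak in both replicates, where 306.4 and 126.9 genes were expected (adjusted permutation p = 0.000483 for each). The Hox genes, which set position along the body axis, had 0 of 39 marked against 5.29 expected (adjusted permutation p = 0.0162), and a peak in both replicates in 1 gene against 10.8. Hoxb5 had 10.7% coverage in replicate 1 and 0% in replicate 2, and Hoxb4 had 0% and 6.08%. The Hox call ended when lists were rotated along the genome, which keeps neighbouring genes together (adjusted permutation p = 0.0580), and under 6 other alternatives, over a range of 0.000483 to 1. At 50% coverage both receptor calls ended as well.

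**Figure D3:**
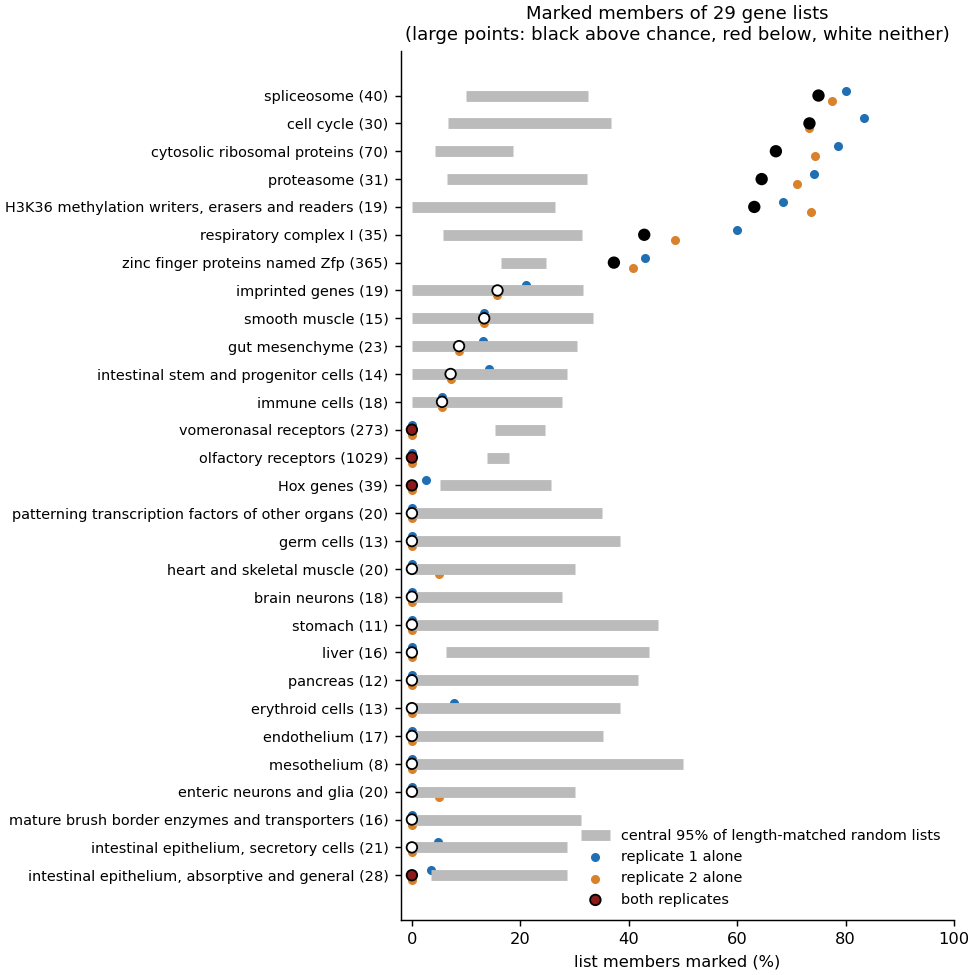
Percentage of the members of 29 gene lists (number measured in brackets) that were marked, with small points for each replicate alone, large points for both replicates together and grey bars for the central 95% of length-matched random lists. The 7 lists above chance had from 37.3% (zinc finger genes named Zfp) to 30 of 40 (spliceosome) of their members marked, and 17 lists had no marked member.

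Imprinted genes were marked in 3 of 19 cases against 2.66 expected (adjusted permutation p = 1). These were Igf2r (chromosome 17, 12682406 to 12769664; 15.9% ± 1.81, SD, n = 2), Impact (13.7% ± 2.30) and Gnas (11.1% ± 0.253), which overlaps another gene. Among noncoding genes, Malat1, a nuclear RNA, had 25.7% and 12.5% coverage in replicates 1 and 2, Meg3 had 5.86% ± 0.667, H19 had 0% in both, and Xist, the RNA that coats the inactive X, had 0% and 1.57%.

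X-linked genes were marked far less often than autosomal genes. On X, 3 of 877 genes were marked (0.342%, Wilson 95% interval 0.116 to 1.00), compared with 3324 of 20181 (16.5%) on the autosomes, which ranged from 10.4% on chromosome 14 to 22.3% on chromosome 8. Peaks were fewer too, with 3.50 per Mb in replicate 1 and 4.33 in replicate 2 against 28.7 to 70.8 on the autosomes. A peak in both replicates was found in 17.6% of X-linked genes and in 39.5% to 57.9% of the genes of each autosome. The 3 marked genes, named after their values were seen, were Kdm5c, a histone demethylase gene that escapes X inactivation (152233020 to 152274535, 16.6% ± 2.35, SD, n = 2), Gm21887 (170009659 to 170019281, 19.2% ± 0.140), and the melatonin synthesis gene Asmt (170672644 to 170678054, 35.4% ± 4.82). Gm21887 and Asmt lay near the end of X, which is 171031299 bases long. The marked share on X was 0.0208 times that of the autosomes, and 0.0456 times in replicate 1 alone and 0.0641 times in replicate 2 alone. X is 1 of 20 chromosomes, so no two-sided test over chromosomes could reach a p below 0.1; over the other alternatives the ratio lay between 0 and 0.0825.

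**Figure D4:**
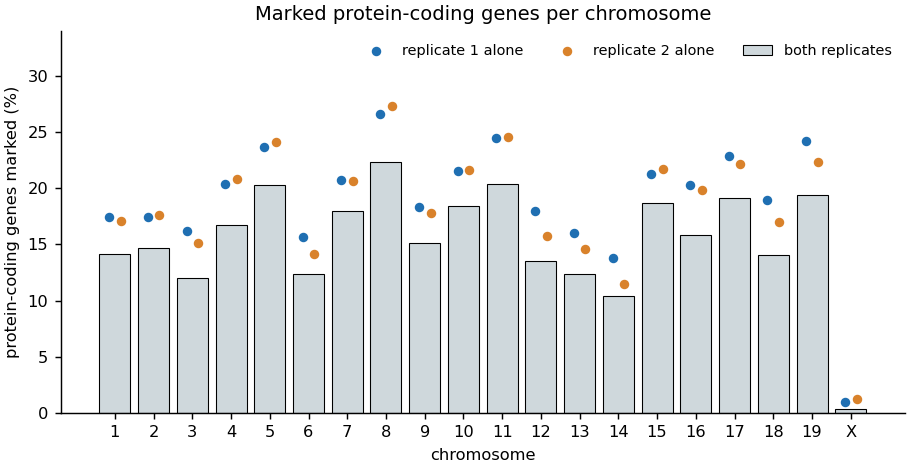
Percentage of protein-coding genes marked on each chromosome, with bars for both replicates together and points for each replicate alone. Autosomes lie between 10.4% and 22.3% and X at 0.342%.

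Genes of intermediate length were marked most often. The share was 9.13% (307 of 3364) at 1 to 5 kb, 21.0% (1599 of 7626) at 5 to 20 kb, 18.1% (1374 of 7579) at 20 to 100 kb and 1.89% (47 of 2489) above 100 kb. A peak in both replicates was found in 16.02%, 41.7%, 63.3% and 64.9% of these classes, so the longest genes often had a peak and were rarely covered over 10%. The share at 5 to 20 kb was 11.1 times that above 100 kb, and between 2.13 times, with gaps of up to 3 kb joined, and 126 times, at 25% coverage, under the alternatives. Long intergenic noncoding RNA genes were marked in 49 of 4953 cases (0.989%) and processed pseudogenes in 19 of 2110 (0.900%). Of those outside protein-coding bodies, 15 of 4495 (0.334%) and 4 of 1757 (0.228%) were marked. Antisense genes were marked in 182 of 2718 cases (6.70%), and 0 of the 182 antisense genes that lie outside protein-coding bodies were marked.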

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

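The counts here were taken after the lists were seen, and none was tested. Unplaced and unlocalised scaffolds, which no comparison used, held 30 peaks in replicate 1 and 36 in replicate 2. Of these, 6 and 7 lay on 1 scaffold assigned to chromosome 4, where the highest fold values were 12.2 and 11.9. The Y chromosome, also left out of the comparisons, held 7 peaks in replicate 1 and 5 in replicate 2. All but 1 of them lay between 90738731 and 90745553, in no annotated protein-coding gene, and the other was in Ddx3y in replicate 1, with a fold value of 3.98.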

How the results depend on the processing

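Autosomal genes only and random lists matched on GC content or on GC content and repeats were chosen after the data were seen; the others were set before. The share of peak bases in gene bodies (93.4% to 95.1%) and the 3' over 5' ratio (1.55 to 2.21) kept their direction and call under every alternative run for them. The exon over intron ratio kept its call under 13 of 14 alternatives. The 7 lists above chance were called under 18 of 18 alternatives for Zfp, 17 for ribosomal proteins, spliceosome, proteasome and cell cycle, 16 for H3K36 enzymes and readers and 14 for complex I. Stem and progenitor cells, smooth muscle, mesenchyme, immune cells and imprinted genes stayed without a call under all 18. The depth of the libraries is unknown, so a peak that is absent cannot be told from one too weak to be called. The causes of the changes below were not tested.

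With peaks of -log10 q of at least 2, base overlap of the replicates was 17.4%, shared peaks 26.3%, marked genes 1548, the ratio of marked shares at 5 to 20 kb over more than 100 kb 46.7, and 2 lists lay below chance. Calls were lost for absorptive epithelium (0), Hox genes (0), complex I (4) and H3K36 enzymes and readers (4). With fold of at least 3, base overlap was 18.6%, shared peaks 28.4%, the length ratio 22.6, and 2 lists lay below chance. Absorptive epithelium (0), Hox genes (0) and complex I (9) lost their calls. With gaps of up to 1 kb joined, base overlap was 32.0%, shared peaks 30.6%, the X over autosome ratio 0.0443, the length ratio 4.40, and 8 lists lay below chance. Absorptive epithelium (2) lost its call, and brush border, endothelium, liver, heart and muscle and patterning factors (0 each) gained one below chance. With gaps of up to 3 kb joined, base overlap was 46.8%, shared peaks 35.99%, marked genes 6323, the X ratio 0.0803, the length ratio 2.13, and 12 lists lay below chance. Absorptive epithelium (9 against 8.09 expected) turned direction without a call. Brush border, enteric neurons and glia, endothelium (1 each), pancreas, liver, brain, heart and muscle, germ cells and patterning factors (0 each) came to lie below chance.

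Shared peaks were 44.9% when 1 base of overlap sufficed and 22.5% with reciprocal overlap of 50%. Leaving out a replicate gave X ratios of 0.0456 to 0.0641, length ratios of 9.35 to 11.1, absorptive epithelium counts of 0 to 1, with the call lost in replicate 1 alone, and liver counts of 0 both times, with a call below chance each time. The pooled list gave 5038 marked genes, an X ratio of 0.0825, a length ratio of 6.03 and 9 lists below chance, which took in brush border, endothelium, liver, heart and muscle and patterning factors (0 each). The replicated list gave a length ratio of 16.2. Restricted to genes overlapping no other gene, or to genes of at least 5 kb, 2 lists lay below chance each time, without absorptive epithelium (0) and Hox genes (0), with fewer genes tested. Rotation of lists along the genome also left 2 below chance, without absorptive epithelium (0) and Hox genes (0). Random lists matched on GC content, and on GC content and repeats, kept 7 lists above chance and put 5 below, with patterning factors (0) added.

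Marked at 5%, 5612 genes passed, with an X ratio of 0.0699, a length ratio of 3.45 and 10 lists below chance. Absorptive epithelium (5) lost its call, and brush border, endothelium, liver, brain, heart and muscle, germ cells and patterning factors (0 each) gained one below chance. At 25%, 621 genes passed, with an X ratio of 0.0371, a length ratio of 126 and 2 lists below chance. Absorptive epithelium (0) and Hox genes (0) lost their calls and complex I (1 against 1.40 expected) turned direction. At 50%, 14 genes passed, with an X ratio of 0, an exon over intron ratio of 1.11, 1 list above chance and 0 below. No gene above 100 kb was marked there, so the length ratio had no value. Ribosomal proteins, spliceosome, proteasome, complex I, cell cycle and H3K36 enzymes and readers (0 each) turned direction, and absorptive epithelium, Hox genes, olfactory and vomeronasal receptors (0 each) lost their calls, where so few marked genes leave under 1 expected. With any peak in both replicates, 10133 genes passed and 15 lists lay below chance. Absorptive epithelium (17 against 12.1 expected) turned direction. Secretory epithelium, enteric neurons and glia, erythroid cells, brain, heart and muscle (2 each), endothelium (4), germ cells (1), mesothelium, pancreas, liver, stomach and patterning factors (0 each) came to lie below chance.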

Other observations

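The survey of gene families, the tests on ubiquitous and escape genes of X, on gut against other-organ genes and on introns of zinc finger genes were chosen only after the results were seen; the matched draws for X and the alternatives for zinc finger genes were set before their results.

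Besides the fixed lists, 146 families of at least 15 protein-coding genes that share the stem of their symbol were surveyed in the same way, and 18 lay above chance and 9 below. Families can share members with the fixed lists. The 18 include Rpl (27 of 48) and Rps (21 of 42), which overlap the ribosomal protein list, and Ddx, which shares members such as Ddx23 with the spliceosome list. Translation initiation factors (Eif) were marked in 35 of 54 cases against 9.91 expected, RNA helicases (Ddx) in 24 of 36 against 7.34, RNA polymerase subunits (Polr) in 16 of 28 against 5.03 and Mediator subunits (Med) in 16 of 30 against 4.90. Mitochondrial ribosomal proteins of the large subunit (Mrpl) followed with 20 of 46 against 7.69, nucleoporins (Nup) with 12 of 21 against 3.36, and the vacuolar sorting family Vps with 16 of 35 against 5.64. The families Cdc (16 of 33 against 5.80) and Cep (16 of 36 against 5.64) were also above chance. Adjusted permutation p was at most 0.00547 for these 9. Of the 18, 14 stayed above chance with rotation along the genome and in each replicate. Mitochondrial ribosomal proteins of the small subunit (Mrps), with 10 of 29 against 4.96, had no call (adjusted permutation p = 0.104).

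Among the 9 families below chance, cytochrome P450 genes (Cyp) were marked in 2 of 100 cases against 19.7 expected, genes with the stem Cd in 4 of 99 against 17.7, those with the stem Il in 4 of 82 against 13.9 and serine proteases (Prss) in 0 of 39 against 6.67. These 4 also stayed below chance with rotation and in each replicate. Keratins (0 of 53 against 9.06) and solute carriers (41 of 371 against 64.5) did not with rotation (adjusted permutation p = 0.143 and 0.0678). By deposited score, the highest-ranked peak of replicate 1 and of the pooled list lay in Mid1 on X, from 169987411 to 169987922 in replicate 1, with a fold value of 10.3. By the same measure the highest of replicate 2 lay in Zfp260 on chromosome 7, from 30103858 to 30105978, with a fold value of 12.9.

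Few X-linked genes were marked, 3 of 877. GC content, repeats and length are excluded as the whole cause, since the central 95% of autosomal draws matched on them began at 81 marked genes. A lack of ubiquitous genes on X did not account for it among the genes compared. Of 30 such genes on X 0 were marked, against 146 of 223 autosomal ones (Fisher's exact p = 4.08e-13). A peak in both replicates was present in 83.3% and 93.3% (Fisher's exact p = 0.0711). The sets were not matched on length, and some of the 30, such as Huwe1, exceed 100 kb, a class that was rarely marked. Genes on X are not independent, so these p-values describe the listed genes only. Dosage of X, with 1 active copy per cell, stays open: 1 of 5 genes that escape inactivation was marked against 0 of the 30 (Fisher's exact p = 0.143), and the mean coverage of the 5 was 8.18% ± 6.04 (SD over genes) against 2.71% ± 2.57, and 17.9% ± 10.6 in the autosomal genes. Kdm5c, the marked gene of the 5, was seen before the test was chosen; without it the mean was 6.07% ± 4.36 (exact permutation p = 0.0252 against the 30), and lists without separate sexes or control coverage cannot settle the matter. The other marked genes of X, Gm21887 and Asmt, were neither among the 5 nor among the 30. Whether they escape inactivation or have a copy on Y was not examined, so they were not weighed for or against dosage.

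Lists of gut cell types did not lie above chance. The hypothesis was that their marking is weak, as when a fraction of the cells carries it, and stays under 10% coverage. It was examined on genes with a peak in both replicates, where the peaks need not overlap. The counts of each list by this measure, low in other organs, were known when the comparison was chosen. The comparison therefore describes the lists and gives the hypothesis no independent support. Of 145 genes of gut cell types 65 (44.8%) had a peak in both replicates, against 5 of 110 genes of other organs (4.55%). Permutation within length classes gave p = 0.0002, the smallest it can give. Taken list by list, 5 of 8 lay above the other organs (adjusted permutation p at most 0.0032), while secretory epithelium (2 of 21), enteric neurons and glia (2 of 20) and mesothelium (0 of 8) did not (0.858 or more), so the hypothesis has no support for those 3. For the other 5 the values leave weak marking possible, but cannot tell marking in a part of the cells from weak marking in all of them. The lists hold no measure per cell, and gut genes did not exceed all genes (48.1%).

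Zinc finger genes named Zfp lay above chance, with 136 marked. Domains shared by neighbouring genes are excluded as the whole cause, since rotation along the genome gave 57.8 expected, and so are GC content, repeats and length, which gave 65.0 expected in matched lists. Reads shared between similar exons cannot be excluded. On introns alone 75 of 351 genes were marked against 59.5 expected (permutation p = 0.03). At least 500 bases from exon edges, 56 of 328 were marked against 34.6 (permutation p = 0.0002, the smallest it can give). The excess was thus not confined to the genes' own annotated exons. These comparisons matched on length only, exons of overlapping genes counted as intron, and reads shared between similar introns were not addressed. Intron coverage of marked Zfp genes was no higher than in other marked genes (16.4% against 16.5% and 15.2% against 15.98% in the replicates), and exon coverage of marked Zfp genes was 39.6% and 37.5% in the replicates against 27.3% and 26.9% in other marked genes, so a part in exons stays open. No biological explanation for the marking of Zfp genes was tested.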
